A study of Arabidopsis thaliana with 11 samples.

How the data were processed

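RNA from whole seedlings of Arabidopsis thaliana, ecotype C24, was hybridised to Affymetrix ATH1 arrays, which read 1 biotin-labelled sample each and measure every transcript with a set of short probes. The 11 arrays comprised diploids (n = 2), triploids with the title code TFE (n = 3), triploids with the title code TME (n = 3) and tetraploids (n = 3), with 2, 3, 3 and 4 chromosome sets. Both triploid codes carried the same source label, a cross of a tetraploid with a diploid, and the labels do not spell the codes out. Array numbers in the titles run in blocks by group, so order of handling and group cannot be told apart. Nothing in the labels says that replicates came from separate sowings, so p-values measure the spread between these arrays, which may be technical.

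The deposited values were linear intensity values, 1 signal per probe set, made with MAS5, per the submitters' processing notes, which give no version. The mean of each array, trimmed by 2% at each end, was 100.01, so every array had been scaled to a common mean. A change in the total RNA of a cell, which a change in ploidy could bring, is therefore not visible in these values: all differences are relative to the rest of the array. No detection calls and no scanner files were used here. The number of arrays, not a read depth, limits the precision. No pair of arrays held identical values.

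Of 22810 probe sets, 64 control probe sets were set aside. Plant signals were floored at 2.279, the percentile 10 of all pooled values, and converted to log2. Probe sets above their array's percentile 40 on at least 2 of the 11 arrays were kept, which left 15075 (66.3%); 0.0597% of their values lay at the floor. Each probe set was fitted with limma 3.58.1 in R 4.3.3 (group means over all 11 arrays, moderated variances with an intensity trend), and calls are 2-sided at a Benjamini-Hochberg adjusted p under 0.05 over the probe sets kept. Adjusted p-values in the text come from this limma fit unless stated otherwise. The slope over chromosome sets was fitted with their number as a covariate, and the triploid mean was set against the midpoint of diploid and tetraploid as a contrast of the same group means.

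Gene names came from the platform annotation through the TAIR10.1 gene table: 13513 plant probe sets had 1 gene, 503 several and 8730 were unnamed, and 13436 of the first kind matched the gene table. Among the probe sets kept these numbers were 8161, 293 and 6621. Probe sets with several genes or none carry no gene name in the text. The build behind the array design is not given in the sources used here, so no coordinates are printed. Many well-studied loci are unnamed in this annotation: FLC, CCA1, LHY and PR1, meant to be given in every comparison, have 0 named probe sets.

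The genes named follow a fixed rule. Per comparison with the diploids, and between the triploids, these were the 8 largest rises and 8 largest falls among probe sets with 1 gene that were called, did not overlap between the groups' arrays and had a brighter group mean above the median of all probe sets kept (signal 84). Up to 3 called members of each gene list were added. Where fewer than 5 probe sets were called, the 10 with the smallest p were taken. For the slope and the midpoint contrast, 5 rises and 5 falls were taken without the condition on overlap, and the same 10 by p where fewer than 5 were called. The groups, comparisons, this rule, 32 gene lists of 668 loci and the other settings listed below were set before the data were examined.

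Gene lists with at least 5 measured members, 1 probe set per gene, were tested with camera from limma, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, in 6 comparisons. List results for other settings and with arrays left out used the preset correlation unless stated otherwise. Of 36 lists, 29 had fewer members and were not tested. The 7 tested were nuclear photosynthesis genes, cell wall expansion, flavonoid and anthocyanin synthesis, cytosolic ribosomal proteins, histones, the chloroplast genome and the mitochondrial genome. The ribosomal and histone lists were planned from gene descriptions, which the gene table lacks. They were written by locus after the annotation was seen and before they were tested, and a planned list of transposable elements could not be made. Families of at least 10 named probe sets were tested after the first results were seen.

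For each polyploid array, the median deviation from the diploid mean was taken per chromosome, less that of all nuclear probe sets, with 1000 bootstrap draws for its 95% interval, and groups were compared with 2-sided exact permutation tests. The overlap of calls that share the diploid arrays was set against 100 simulated sets of unchanged groups and against independent lists. The level of 18 probe sets of spiked-in bacterial hybridisation controls served as a measure of the array. The fit was tested on simulated data with a seeded set of changed probe sets. For tetraploid versus diploid with 15075 probe sets it recovered 29.9% of 2-fold and 83.3% of 4-fold changes, and 4.44% of its 90 calls were false. For triploid TFE versus triploid TME it recovered 43.3% of 2-fold and 86.4% of 4-fold changes, and 4.81% of 104 calls were false.

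Alternatives were quantile normalization, no filter, a filter at percentile 60, log2 of the signal plus the floor, no intensity trend, robust variances, array weights, only the arrays of the groups compared, the replicate number as a block, a fold of at least 2, and leaving out each array in turn. A fit with the spiked-in control level as a covariate was added after the data were seen.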

Results

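Transcript levels were measured in whole seedlings of the Arabidopsis ecotype C24 at a single early leaf stage, grown on agar, to ask how the transcriptome responds to a change in the number of chromosome sets. There were 2 diploid, 3 triploid TFE, 3 triploid TME and 3 tetraploid arrays. The tetraploids were obtained with colchicine, and the triploids by crossing a tetraploid with a diploid. Rank correlations over the 15075 probe sets kept ran from 0.942 to 0.973 among 10 of the arrays. The remaining array, triploid TFE replicate 3, reached 0.861 to 0.88 with the others.

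The widest ploidy step, tetraploid versus diploid, changed 125 probe sets, of which 90 were higher and 35 lower in tetraploids, with a median absolute log2 difference of 1.14. ORA47, a transcription factor of the AP2/ERF family linked to jasmonate, rose most: its signal was 268 ± 47.3 (SD, n = 3) in tetraploids and 17.1 ± 9.65 (SD, n = 2) in diploids, a log2 difference of 4.09 ± 0.36 (SE; limma, adjusted p = 8.2e-05). Both diploid signals, 23.88 and 10.23, lay below the percentile 40 of their array (26.4 and 27.4). The size of every ORA47 difference from diploids, and of its slope, is therefore uncertain. PUB19, a U-box E3 ubiquitin ligase, rose by 2.54 ± 0.36 (adjusted p = 0.003). AR781, 1 of 4 measured members of the list of touch, wound and early stress genes, rose by 1.62 ± 0.23 (adjusted p = 0.003), while the zinc-finger gene STZ of the same list had a difference of 1.58 ± 0.36 that missed the threshold (adjusted p = 0.064). Of the 4 members, 3 were higher in tetraploids, and only AR781 was called. AT3G15450, AT2G20670, AT5G60680, AT1G76600 and AT3G07350 rose by 1.97, 1.85, 1.61, 1.57 and 1.57.

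Fewer transcripts were lower in tetraploids than in diploids. AT4G36700 fell from a signal of 107 ± 42.2 (SD, n = 2) to 10.8 ± 8.57 (SD, n = 3), a log2 difference of -3.73 ± 0.78 (SE; limma, adjusted p = 0.036) that is no exact value, since a tetraploid array lay at the floor. TBL26, of the trichome birefringence-like family, had a difference of -1.35 ± 0.22 (adjusted p = 0.0075), and EXGT-A3, a xyloglucan endotransglucosylase, had -0.68 ± 0.13 (adjusted p = 0.026). AT4G21870, AT1G11700, AT3G44450, AT5G55620 and AT3G24190 lay between -1.53 and -0.72. Without diploid replicate 1, diploid replicate 2, tetraploid replicate 1 or tetraploid replicate 3 the number of calls was 42, 29, 62 or 51, and without triploid TFE replicate 3, which enters only through the shared variance, it was 253. With weights for array quality it was 271. The 3-prime to 5-prime ratio of actin, a sign of RNA quality, also separated these groups (0.506 and 0.524 in diploids, 0.308 to 0.403 in tetraploids), while those of GAPDH and ubiquitin overlapped.

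No gene list passed the test in this step (camera, preset correlation). All 6 measured flavonoid and anthocyanin genes were lower in tetraploids, with a median of -0.31 and an adjusted p of 0.0538, or 0.2 with an estimated correlation. The chloroplast genome had 44 of 69 transcripts higher (median 0.12, adjusted p = 0.0746) and the cytosolic ribosomal proteins 47 of 109 (median -0.03, adjusted p = 0.0956). Nuclear photosynthesis genes had a median of 0.02, a mean of -0.07 and a test pointing down (adjusted p = 0.59). The cell wall expansion list had a median of -0.20 and a mean of -0.03 while its test pointed up (adjusted p = 0.76). The 8 histone and 8 mitochondrial transcripts measured did not pass either (adjusted p = 0.67 and 0.59), and their medians of -0.013 and 0.012 had the opposite sign of their means of 0.016 and -0.052, with both tests pointing down. Adjusted over the list alone, 1 histone gene was higher, 1 lower, and 1 photosynthesis gene lower.

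These list results, with the preset correlation of 0.01, turned on single arrays. The correlations estimated in this comparison were 0.44 for the chloroplast list, 0.5 for photosynthesis and 0.36 for the mitochondrial list. They were 0.22 for the ribosomal and -0.031 for the flavonoid list. Where the estimate lies far above the preset, the p-values given here can be far too small. Without diploid replicate 1, the photosynthesis, flavonoid, ribosomal and chloroplast lists all passed, with medians of -0.16, -0.47, -0.036 and -0.063 (camera, adjusted p = 0.0067, 0.015, 0.033 and 0.033), while without diploid replicate 2 the chloroplast list passed with 0.26 (adjusted p = 4.8e-10). The flavonoid list also passed without triploid TFE replicate 1, 2 or 3, triploid TME replicate 2, tetraploid replicate 1 or tetraploid replicate 3 (adjusted p = 0.04, 0.046, 0.045, 0.032, 0.049 and 0.022). The chloroplast list passed without triploid TME replicate 2, tetraploid replicate 2 or tetraploid replicate 3 (adjusted p = 0.029, 0.00013 and 0.025), the ribosomal list without tetraploid replicate 3 (adjusted p = 0.025) and the mitochondrial list without tetraploid replicate 1 (median -0.32, adjusted p = 0.049).

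**Figure D1:**
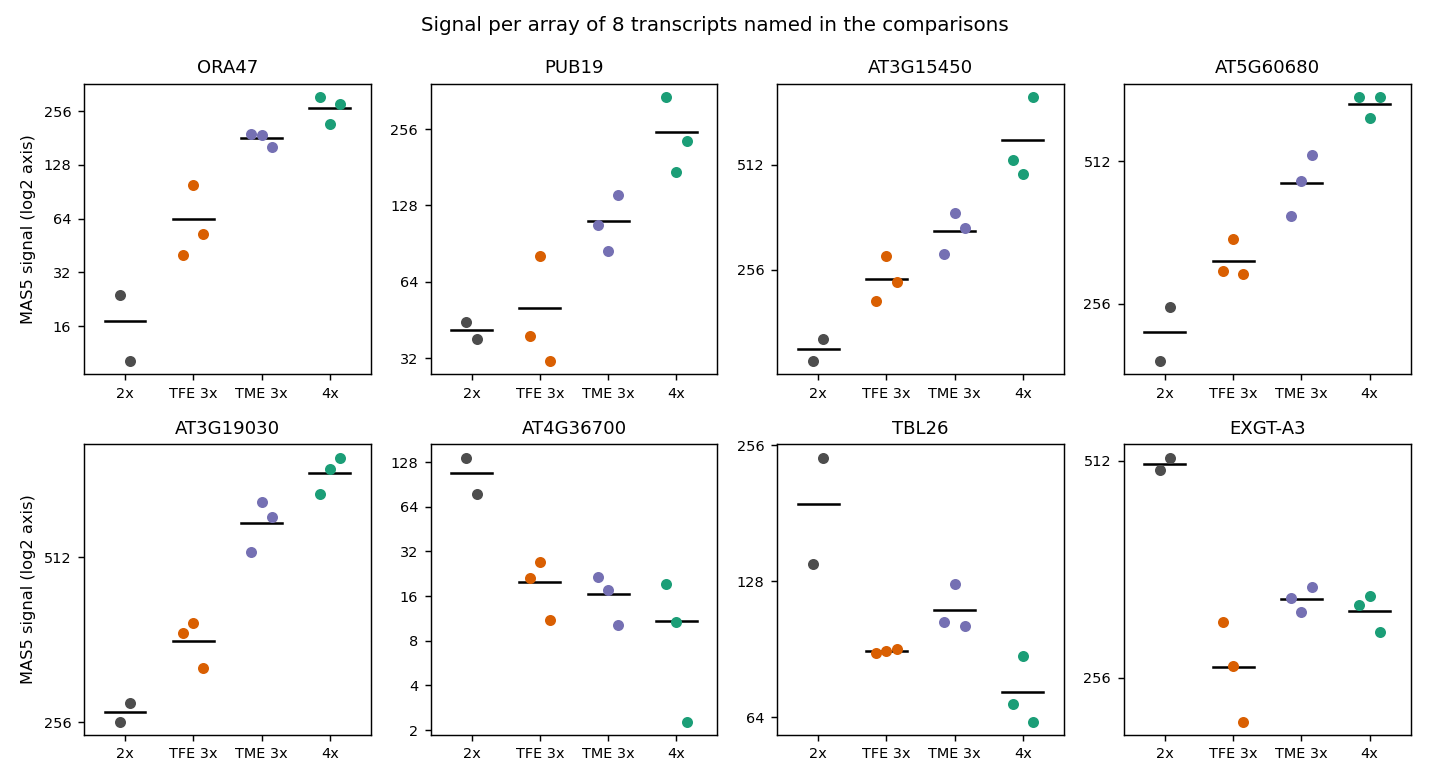
MAS5 signal on a log2 axis of 8 named transcripts, 1 point per array and a line at the mean of the linear signals of each group (diploid 2x, triploid TFE, triploid TME, tetraploid 4x). The group means of ORA47 were 17.1, 63.8, 180 and 268 in that order, and those of EXGT-A3 were 507, 265, 329 and 317.

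The step from 2 to 3 sets was tested separately for each triploid code. In triploid TME 19 probe sets were called, all of them higher than in diploids, and 9 of them had 1 gene. ORA47 again led, with a signal of 180 ± 16.8 (SD, n = 3) and a log2 difference of 3.52 ± 0.36 (SE; limma, adjusted p = 0.00064). AT1G76600, AT3G19030, AT3G15450, AT3G07350 and AT5G60680 were higher by 1.39, 1.14, 1.13, 1.11 and 1.05, and AT3G56880, a VQ-motif gene, by 0.98. AT4G17470 completed the named genes with 0.84 ± 0.15 (adjusted p = 0.043). The number of calls varied from 1 without the intensity trend to 89 with array weights. Without diploid replicate 1 or 2 it was 2 or 4, without triploid TME replicate 1, 2 or 3 it was 4, 5 or 4, without tetraploid replicate 1, 2 or 3 it was 11, 6 or 12, and without triploid TFE replicate 1, 2 or 3 it was 11, 31 or 57.

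All 19 of these probe sets were also among the 90 called higher in tetraploids. Independent lists would share 0.11. Simulated unchanged groups set against the same 2 diploid arrays shared 0.02 on average. Unchanged groups give few calls to share, so that value is no expectation for lists of 90 and 19. Part of the overlap may come from the shared diploid arrays, which are too few to split. Across probe sets, which are not independent replicates, the log2 differences of tetraploids and of triploid TME correlated with r = 0.67, against 0.6 in the simulation. Their covariance was 0.073 against a simulated 0.07, a difference of 0.0027. The pairs with triploid TFE lay below the simulation: tetraploid and TFE differences correlated with r = 0.47 against 0.6 (covariance 0.068 against 0.07), and TFE and TME differences with r = 0.43 against 0.6 (covariance 0.051 against 0.07). The simulation gave the same values for every pair, so it makes no allowance for the outlying triploid TFE replicate 3 (rank correlations 0.861 to 0.88). Independent noise on that array could lower r by itself, though not the expected covariance. The covariance differed from the simulation by -0.019 for TFE and TME, and by -0.0019 for tetraploid and TFE. No spread of the simulated covariance is given, so the shortfall does not show that TFE responded otherwise.

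Lists in triploid TME versus diploid showed small shifts. The chloroplast genome had 60 of 69 transcripts higher with a median of 0.19 (camera, adjusted p = 4.56e-07; adjusted p = 0.86 with an estimated correlation). Without diploid replicate 1 the median was -0.028 (adjusted p = 0.72) and without diploid replicate 2 it was 0.38, so this shift depends on diploid replicate 1. It also turned, to -0.049 (adjusted p = 0.3), with the level of the spiked-in hybridisation controls in the fit, whose mean signal was 336 in triploid TME and 239 in diploids. Flavonoid and anthocyanin genes fell as a list, with 5 of 6 lower, a median of -0.33 and an adjusted p of 0.0374 (adjusted p = 0.24 with an estimated correlation). Among them DFR, dihydroflavonol reductase, had a difference of -0.58 ± 0.24 with an adjusted p of 0.97. None of the 6 passed when adjusted over the list alone. Ribosomal proteins, photosynthesis, cell wall, histone and mitochondrial genes did not pass (adjusted p = 0.12, 0.57, 0.66, 0.83 and 0.83), and 1 histone gene was higher when adjusted over the list alone. The cell wall list had a median of -0.0038 and a mean of -0.0069 while its test pointed up, the histones a median of -0.048 and a mean of 0.029 with a test pointing down, and the mitochondrial list a median of -0.031 and a mean of 0.077 with a test pointing up. The flavonoid call was lost without diploid replicate 1, diploid replicate 2, triploid TME replicate 1 or triploid TME replicate 2 (adjusted p = 0.054, 0.27, 0.071 and 0.068), and without diploid replicate 2 the photosynthesis and ribosomal lists passed (adjusted p = 0.00012 and 0.03).

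In triploid TFE no probe set was called against the diploids (limma, 0 at an adjusted p under 0.05, 1369 at an unadjusted p under 0.05, smallest adjusted p 0.057). The 10 named genes with the smallest p are therefore given as not past the threshold. EXGT-A3 had a signal of 265 ± 41.7 (SD, n = 3) against 507 ± 13.7 (SD, n = 2) in diploids, a log2 difference of -0.95 ± 0.13 (adjusted p = 0.057). Of the others, 6 belong to the chloroplast genome: rpl33, rps14 and rps18 for ribosomal proteins, ndhC and ndhG for the NDH complex and psbI for photosystem II, with differences of 0.83, 1.29, 0.72, 0.72, 1.58 and 0.65. ORA47 had a difference of 1.92 ± 0.36 (adjusted p = 0.16), AT4G17470 0.75 ± 0.15 (adjusted p = 0.16) and the dim AT1G42220 3.28 ± 0.63 (adjusted p = 0.16), no exact value since a diploid array lay at the floor. EXGT-A3 and rpl33 passed the threshold under quantile normalization, the stricter filter, robust variances and array weights, with differences between -0.95 and 0.85. Without triploid TFE replicate 1, triploid TFE replicate 3 or triploid TME replicate 2 the number of calls was 6, 3 or 4.

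As a list, the chloroplast genome rose in triploid TFE: all 69 transcripts were higher, with a median of 0.50 (camera, adjusted p = 1.49e-35), though not with an estimated correlation (adjusted p = 0.075). Adjusted over the list alone, 33 of the 69 were higher. With the level of the spiked-in controls in the fit the median turned to -0.0019 (adjusted p = 0.055). Without triploid TFE replicate 3, the array that stood apart, the median was 0.50 as before, while without diploid replicate 1 it was 0.32 and without diploid replicate 2 it was 0.72. The spiked-in hybridisation controls had their highest group mean in triploid TFE, at 531 ± 139 (SD, n = 3), against 336 ± 79.3 (SD, n = 3) in triploid TME, 250 ± 7.72 (SD, n = 3) in tetraploids and 239 ± 116 (SD, n = 2) in diploids. Single arrays overlapped, with triploid TME replicate 1 at 425 and triploid TFE replicate 1 at 372. The actin 3-prime to 5-prime ratio was also higher on every triploid TFE array (0.559 to 0.92) than in diploids (0.506 and 0.524), while those of GAPDH and ubiquitin overlapped. Over the 11 arrays the chloroplast level correlated with the control level, with r = 0.882 (permutation p = 0.00042) and rho = 0.845 (permutation p = 0.0019). Without the 2 arrays farthest from the median control level r was 0.799 (permutation p = 0.0086), and with group means removed it was 0.716 (exact permutation within groups, p = 0.014). This pair of measures was chosen after the values were seen.

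**Figure D2:**
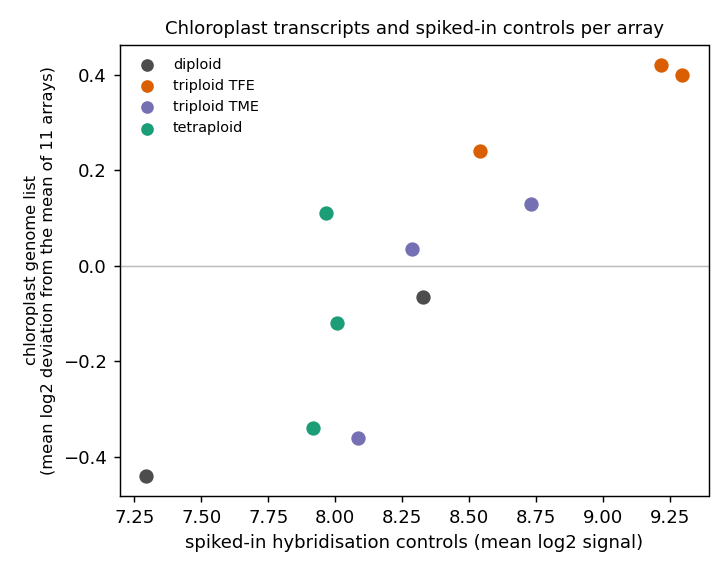
Mean log2 deviation of 69 chloroplast transcripts from their mean over 11 arrays (y axis) against the mean log2 signal of the spiked-in hybridisation controls (x axis), 1 point per array, coloured by group. The 3 triploid TFE arrays, at 0.24, 0.42 and 0.40, lie above all others.

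Other lists differed less in triploid TFE. Flavonoid and anthocyanin genes fell as a list, with all 6 lower and a median of -0.54 (adjusted p = 0.011, and 0.075 with an estimated correlation). Their members included DFR at -0.68 ± 0.24 and the flavonoid glucosyltransferase UGT78D2 at -0.45 ± 0.18, neither past the threshold (adjusted p = 0.48 and 0.51), and none passed when adjusted over the list alone. The call was lost without diploid replicate 2, where the adjusted p was 0.15. Nuclear photosynthesis genes had 7 of 8 members higher and a median of 0.22 with an adjusted p of 0.0499, which was 0.69 with an estimated correlation and 0.87 under quantile normalization. With the spiked-in control level in the fit the median turned to -0.11 (adjusted p = 0.055). The call was lost without diploid replicate 1, triploid TFE replicate 1, triploid TFE replicate 2, triploid TME replicate 1, triploid TME replicate 3 or tetraploid replicate 2 (adjusted p = 0.96, 0.082, 0.22, 0.052, 0.066 and 0.054). The light-harvesting gene LHCB4.3 went the other way at -0.52 ± 0.16 and was the 1 gene lower when adjusted over the list alone. Mitochondrial, cell wall, histone and ribosomal lists did not pass (adjusted p = 0.3, 0.74, 0.91 and 0.97), though 1 cell wall gene was higher when adjusted over the list alone and the ribosomal list passed without triploid TFE replicate 3 (median 0.078, adjusted p = 0.0095). The cell wall list had a median of -0.03 and a mean of 0.065 with a test pointing up, and the histones a median of -0.063 and a mean of 0.016 with a test pointing down.

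Whether the triploid codes differ was tested directly, triploid TFE versus triploid TME. There were 4 calls, 1 higher and 3 lower in TFE. The chloroplast gene rpl33 was the single call with 1 gene, with a signal of 1600 ± 109 (SD, n = 3) in TFE and 958 ± 92.8 (SD, n = 3) in TME and a log2 difference of 0.74 ± 0.11 (SE; limma, adjusted p = 0.039). The other calls were unnamed probe sets, all lower in TFE, with differences of -2.12, -1.13 and -0.90 (adjusted p = 0.039, 0.039 and 0.048). They are given here although they fall outside the rule for named genes, chosen after their values were seen. Of the 9 other named genes none passed the threshold: the chloroplast genes psbN, psaJ, rps18 and psbI had differences of 2.06, 0.87, 0.60 and 0.53, and AT3G19030, AT3G07350, ORA47, AT2G24550 and AT5G19110 had -0.71, -0.85, -1.60, -0.79 and -2.17.

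The chloroplast genome was the only list called between the triploid codes, with 67 of 69 transcripts higher in TFE, a median of 0.37 and an adjusted p of 4.2e-21, or 0.41 with an estimated correlation. Adjusted over the list alone, 13 were higher. The spiked-in controls (mean signal 531 against 336) and the actin 3-prime to 5-prime ratio (0.559 to 0.92 against 0.407 to 0.539) were higher in TFE too, and with the control level in the fit the median was 0.077 (adjusted p = 9.6e-05; adjusted p = 0.84 with an estimated correlation). Photosynthesis and ribosomal lists had an adjusted p of 0.25 each, and the mitochondrial, flavonoid, histone and cell wall lists 0.34, 0.44, 0.84 and 0.88. Without triploid TFE replicate 2 the ribosomal list passed (median -0.082, adjusted p = 0.036). The 4 calls became 0 under quantile normalization, without the filter, without the intensity trend and with only these 6 arrays in the fit. They also became 0 with the replicate number as a block and with the spiked-in control level in the fit. Since that level differed between the codes, its fit has less power for this comparison. Leaving out triploid TFE replicate 3, any triploid TME array, any diploid or any tetraploid array gave 0 calls too. Without triploid TFE replicate 1 there were 6 calls, 0 of them among the 4 and none higher, so rpl33 was lost, and without triploid TFE replicate 2 there were 6 calls, 3 of them among the 4.

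For the step from 3 to 4 sets, tetraploids had 71 calls against triploid TFE, 58 higher and 13 lower. ORA47, PUB19 and AT3G15450 were higher in tetraploids by 2.17, 2.37 and 1.3 (limma, adjusted p = 0.0073, 0.004 and 0.0045), and the chloroplast genes rps18, rpl33 and psbN had differences of -0.92, -0.77 and -2.11 (adjusted p = 0.0051, 0.0057 and 0.019). These genes were named from other comparisons. Against triploid TME there were no calls (limma, 0 at an adjusted p under 0.05, 697 at an unadjusted p under 0.05), and 2 without triploid TFE replicate 3. The median difference of the 90 probe sets higher in tetraploids than in diploids was 0.82 from triploid TFE to tetraploid and 0.35 from triploid TME to tetraploid. These probe sets were selected for a high tetraploid level, which by itself favours a rise in both steps. Without tetraploid replicate 1 or tetraploid replicate 3 the 71 calls became 22 or 13, and without triploid TFE replicate 1 they became 126. With the spiked-in control level in the fit they became 0. That level was higher on every triploid TFE array (372 to 627) than on every tetraploid array (242 to 257). The fit therefore has little power to separate group and control level, and the fall to 0 does not decide between them.

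Over the dosage series of 2, 3, 3 and 4 sets, 64 probe sets had a called slope, 46 rising and 18 falling. Nearly all of them were also called in tetraploid versus diploid, so the slope largely restates that step. The triploid codes, both with 3 sets, could lie apart: the mean signal of ORA47 was 63.8 in TFE and 180 in TME. ORA47 rose by 1.97 ± 0.31 log2 units per chromosome set (SE; limma, adjusted p = 0.012), PUB19 by 1.32 ± 0.26 (adjusted p = 0.031), AT3G15450 by 0.99 ± 0.11 (adjusted p = 0.0017), AT5G60680 by 0.81 ± 0.10 and AR781 by 0.81 ± 0.15. Among the falling slopes, those with 1 gene were AT4G21870 at -0.74 ± 0.12, TBL26 at -0.65 ± 0.12, AT3G44450 at -0.56 ± 0.10 and AT5G55620 at -0.37 ± 0.06. The number of slopes was 6, 22, 22, 40 and 7 without diploid replicate 1, diploid replicate 2, tetraploid replicate 1, tetraploid replicate 2 and tetraploid replicate 3, and 226 without triploid TFE replicate 3.

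No list had a called slope. Flavonoid and ribosomal genes were nearest (medians -0.13 and -0.03 per set, adjusted p = 0.0563 for each), and the chloroplast genome had a median slope of 0.02 (adjusted p = 0.72). The mitochondrial, photosynthesis, histone and cell wall lists had adjusted p = 0.4, 0.4, 0.72 and 0.86, the histones with a median of -0.0033 and a mean of 0.0063 and a test pointing down, the cell wall list with a median of -0.094 and a test pointing up. Without diploid replicate 1 the photosynthesis, ribosomal and chloroplast lists passed with medians of -0.11, -0.034 and -0.093 (adjusted p = 0.00074, 0.0024 and 1.5e-05), and without tetraploid replicate 2 the chloroplast list passed with 0.071 (adjusted p = 0.00056). The flavonoid list passed without tetraploid replicate 1 or tetraploid replicate 3 (adjusted p = 0.046 and 0.019), and the ribosomal list without tetraploid replicate 3 (adjusted p = 0.038). For the histones, 1 gene rose and 1 fell when adjusted over the list alone, and 1 photosynthesis gene fell. All list tests of the slope given here used the preset correlation, with or without an array left out. The estimated correlations were 0.63 for the chloroplast, 0.48 for the photosynthesis and 0.2 for the ribosomal list.

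No probe set was called off the midpoint of diploid and tetraploid in the triploids (limma, 0 at an adjusted p under 0.05, 813 at an unadjusted p under 0.05). This does not show that none lay off it. Only 2 diploid arrays enter, and the contrast averages both triploid codes, so opposite deviations could cancel. The 10 genes with the smallest p, none past the threshold, held 5 ribosomal protein genes of the chloroplast genome, rps18, rpl33, rps19, rps14 and rpl32, with differences of 0.52, 0.43, 0.45, 0.73 and 0.48. The others were ndhC at 0.41, AT1G22520 at -0.50, EXGT-A3 at -0.45, AT4G23670 at 0.32 and AT1G42220 at 1.85, again with a diploid array at the floor. As lists, the chloroplast genome with 69 of 69 higher, nuclear photosynthesis with 7 of 8 higher and cytosolic ribosomal proteins with 65 of 109 higher lay above the midpoint, with medians of 0.30, 0.16 and 0.02 (adjusted p = 1.78e-35, 0.00343 and 0.00668; adjusted p = 0.15, 0.35 and 0.57 with an estimated correlation). Triploid TFE carried most of the chloroplast excess: the mean levels of the list, relative to all arrays, were 0.35 in TFE, -0.066 in TME, -0.12 in tetraploids and -0.25 in diploids. With the spiked-in control level in the fit the chloroplast and photosynthesis medians changed sign, to -0.028 and -0.034 (adjusted p = 0.85 and 0.23). Quantile normalization ended the photosynthesis and ribosomal calls (adjusted p = 0.41 and 0.11). Flavonoid, mitochondrial, cell wall and histone lists did not pass (adjusted p = 0.0569, 0.0569, 0.52 and 0.82), the histones with a median of -0.017 and a mean of 0.015 and a test pointing up. Adjusted over the list alone, 22 chloroplast transcripts were higher.

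With the preset correlation, the midpoint calls of the smaller lists also turned on single arrays. Photosynthesis was lost without diploid replicate 1 (adjusted p = 0.29), and ribosomal proteins without diploid replicate 1, triploid TFE replicate 1, triploid TFE replicate 2 or tetraploid replicate 1 (adjusted p = 0.051, 0.19, 0.18 and 0.066). The flavonoid list passed without diploid replicate 1, triploid TFE replicate 3, triploid TME replicate 3 or tetraploid replicate 2 (adjusted p = 0.049, 0.048, 0.047 and 0.033). The mitochondrial list passed without diploid replicate 2, triploid TFE replicate 1, triploid TME replicate 2, triploid TME replicate 3 or tetraploid replicate 1 (adjusted p = 0.035, 0.021, 0.044, 0.047 and 0.0019).

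A gain or loss of a single chromosome in a polyploid line would shift the transcripts of that chromosome together. Among 45 chromosome medians of 9 polyploid arrays the highest was 0.043, for chromosome 4 of triploid TME replicate 1, and the lowest -0.041, for chromosome 2 of triploid TFE replicate 3. The 95% bootstrap intervals stayed within -0.077 and 0.075. If signal followed gene copy, an extra chromosome would add 0.32 in a tetraploid and 0.42 in a triploid, and a missing chromosome would give -0.42 and -0.58. Group differences lay between -0.022 and 0.015 (30 exact permutation tests, 2-sided, smallest p = 0.1, smallest adjusted p = 1). With 3 arrays against 3 the smallest p possible is 0.1.

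**Figure D3:**
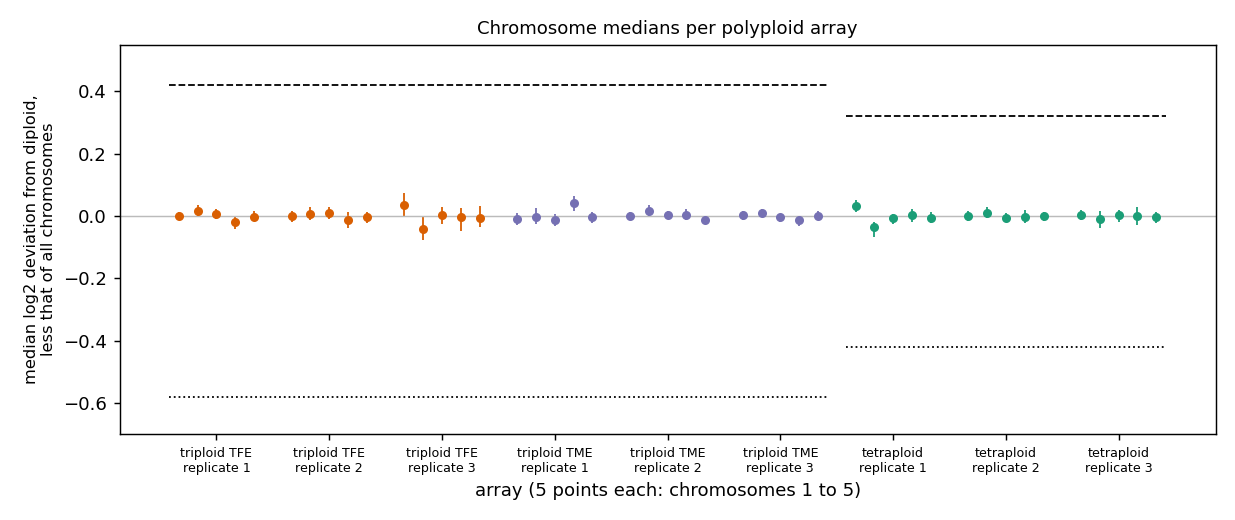
Median log2 deviation from the diploid mean for chromosomes 1 to 5 (points, in order) of each polyploid array, less the median of all nuclear probe sets, with 95% bootstrap intervals. Dashed and dotted lines mark an extra and a missing chromosome if signal followed copy number (0.42 and -0.58 for triploids, 0.32 and -0.42 for tetraploids), and all medians lie between -0.041 and 0.043.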

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

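The tests of the control level, of RNA quality, of the diploid arrays and of handling below were chosen after the results were seen. The test on nuclear photosynthesis genes, the test of the control level on the rising transcripts and the counts of other splits were written before their results were seen. For RNA degradation on triploid TFE replicate 3 the bound for arguing against it was also changed after its value was known, which moved it from argued against to open.

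The direct test between the triploid codes called 4 probe sets and 1 list. Of the probe sets, 3 without a gene name were lower in triploid TFE (-2.12, -1.13 and -0.90) and rpl33 (0.74) was higher, with limma adjusted p between 0.039 and 0.048. The chloroplast genome list had a median difference of 0.37 (camera, adjusted p = 4.2e-21; adjusted p = 0.41 with an estimated correlation). The 4 calls became 0 under quantile normalization, with only these 6 arrays in the fit and with the control level in the fit. The control level differed between the codes, so its fit has less power here. With 10 splits of the 6 arrays no share under 0.05 can be reached: the real split called 4 probe sets, and the highest of the other splits 0. For tetraploid versus triploid TFE the real split called 71 and the highest other 0, and for tetraploid versus triploid TME both were 0, so that all 10 splits gave as many. In each of the former cases 1 of the 10 splits, the real one, gave as many.

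The spiked-in hybridisation controls, which take no part in the comparisons, had a mean signal of 531 in triploid TFE against 239 in diploids, and each of the 3 TFE arrays exceeded both diploid arrays.

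The higher chloroplast transcripts of triploid TFE moved with that control level: with the level as a covariate the median difference from diploids was -0.39% of its size (log2 0.50 before, -0.0019 after), and the correlation within groups was 0.716. These are the values that an effect of labelling needs, but a single scaling factor per array cannot by itself lift 1 list above the other plant transcripts, and how labelling would do so was not tested. More green tissue remains open. The nuclear photosynthesis list had a median of 0.22 (-0.11 with the control level in the fit), below the bound set for it by less than 0.17. That 0.17 is the standard error of the list's mean level, not of its median, so this comparison cannot decide. The mean differences from diploids were 0.13 for this list and 0.61 for the chloroplast list. RNA degradation remains open too. The 3-prime to 5-prime ratio was higher on every TFE array than on all others for 1 of 3 control genes, actin (0.559 to 0.92 against 0.308 to 0.539). These actin ratios lay below 1 and so showed no excess of 3-prime signal, while the highest ubiquitin ratio in TFE was 1.6, against at most 1.29 elsewhere. A real difference between the triploids, which the design names, cannot be separated from these explanations. A single outlying array had also been set out as an explanation and was taken off the list after its value was known: without triploid TFE replicate 3 the median was 0.50.

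Transcripts such as ORA47 rose from diploid over triploid TME to tetraploid. A low level on the diploid arrays alone is argued against for the 19 probe sets called in TME versus diploid: as a set they had a further median rise of 0.305 (SE over arrays 0.069) from TME to tetraploid, with 18 of 19 higher although they were selected for a high TME level, while 0 probe sets were called singly in that step (limma, smallest adjusted p = 0.14). The labelling yield is argued against only for triploid TME, and only as far as the control level tracks it. Mean control signals were close in tetraploids and diploids, at 250 and 239. The control level in the fit could therefore hardly move the tetraploid difference, and the 101% of its median left decides nothing. For TME, with a mean control signal of 336, 94.5% of the median difference was left, although the calls of TME versus diploid went from 19 to 3. Time or handling of harvest stays open, because array numbers run in blocks by group. The touch, wound and early stress list, with 3 of 4 measured members higher, had a median of 1.04 in tetraploid versus diploid. Its only called member, AR781, is itself among the rising transcripts, so the list is no independent sign. An effect of ploidy itself, which the design names, was not separable from handling. RNA quality was not tested for this pattern: the actin ratio was lower on every tetraploid array (0.308 to 0.403) than on every diploid (0.506 and 0.524) and every TME array (0.407 to 0.539), the ubiquitin ratio went the other way against TME (1.01 to 1.29 against 0.906 to 0.995) and overlapped with diploids, and the GAPDH ratio overlapped with both.

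Triploid TFE replicate 3 stood apart from the 10 other arrays. Bacterial control probe sets that were dark elsewhere, at medians from 0.839 to 2.49, had a median of 7.38 on this array. The dimmest plant probe sets were 1.33 log2 units above the mean of the other arrays and the brightest -0.18, which is consistent with a higher background. RNA degradation stays open. The 3-prime to 5-prime ratio of this array was the highest of all for 1 of the 3 control genes, actin (0.92 against at most 0.581). Its ratios for GAPDH (0.919) and ubiquitin (1.06) lay within the range of the others. None of the 3 showed a clear excess of 3-prime signal, so only the rank of actin keeps this open. The 25S ribosomal RNA signal of this array was also the highest, at 677 against at most 334. No biological explanation was tested for a single array.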

How the results depend on the processing

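For tetraploid versus diploid the 125 calls became 78 without the filter, 42 without the intensity trend, 271 with array weights, 198 with only the groups compared, 77 at 2-fold, and 29 to 253 leaving out single arrays. For triploid TFE versus diploid 0 became 2 under quantile normalization, 3 under the stricter filter, 3 with robust variances, 6 with array weights, and 0 to 6 leaving out arrays. For triploid TME versus diploid 19 became 4, 3, 1, 89 and 60 (quantile normalization, no filter, no trend, array weights, only the groups compared), 3 with the control level, and 2 to 57 leaving out arrays. For triploid TFE versus triploid TME 4 became 0 (quantile normalization, no filter, no trend, only the groups compared, the control level), 7 with array weights, 2 at 2-fold, and 0 to 6 leaving out arrays. For tetraploid versus triploid TFE 71 became 20, 3, 19 and 39 (no filter, no trend, only the groups compared, 2-fold), 0 with the control level, and 13 to 126 leaving out arrays. For tetraploid versus triploid TME 0 became 4 with array weights, 1 with only the groups compared, and 0 to 2 leaving out arrays. The slope's 64 calls became 32, 11, 230 and 5 (no filter, no trend, array weights, 2-fold per set), 117 with the control level, and 6 to 226 leaving out arrays. The midpoint contrast stayed at 0 except for 1 without triploid TME replicate 2. The 9 list calls became 14 without the filter, 5 with the control level, 0 with an estimated correlation, and 7 to 14 leaving out arrays; the largest chromosome median moved from 0.043 to 0.052 under the stricter filter. With the replicate number as a block, triploid TME versus diploid had 11 calls and triploid TFE versus triploid TME 0, and no other count moved by over 1.5 times. Same-numbered arrays correlated over 0.1 in 3 of 15 pairs (median 0.025, highest 0.14), and differently numbered arrays in 5 of 30 (median -0.017, highest 0.191). The 3 same-numbered pairs were those of triploid TME and tetraploid, at 0.103, 0.121 and 0.14 against -0.133 to 0.027 for their other numbers. Each array there correlated best with its own number. The 5 pairs of different number over 0.1 all held a diploid array. The deviations of the 2 diploid arrays from their mean mirror each other, so these pairs are no measure of pairing. Outside the diploids the highest correlation of different numbers was 0.0931. A pairing of replicates is thus a weak hint from the data and not the design. Tetraploid versus triploid TME had 0 calls with and without the block. With the control level, chosen after seeing the data, list medians turned to -0.0019 (chloroplast, TFE versus diploid), -0.049 (TME versus diploid) and -0.028 (midpoint), and for photosynthesis to -0.11 (TFE) and -0.034 (midpoint); leaving out single arrays, the chloroplast median of TME ran from -0.028 (without diploid replicate 1) to 0.38 (without diploid replicate 2). Of 734 values of 63 named differences under alternatives, 612 kept their side of the threshold, 106 lost it, 16 gained it and 0 changed sign. Differences never called counted as kept when they stayed so, as did all 109 values of the midpoint contrast. Losses were 39 of 96 values for triploid TME versus diploid, where 0 of 8 genes kept the threshold throughout. They were 36 of 192 for tetraploid versus diploid and 23 of 99 for the slope. From leaving out single arrays, only the lowest and highest value of each difference entered. Fewer or more probe sets tested and fewer arrays explain part of the filter, group and array settings by construction. Where groups differ in the control level, adding it to the fit also widens the errors, so calls can be lost by construction. Otherwise the cause was not tested.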

Other observations

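The tests of gene families in this part were chosen after the data were seen. Among 20 gene families with at least 10 named probe sets, the expansins (EXPA, proteins that loosen cell walls) stood above other genes in tetraploids: all 6 measured members were higher than in diploids, with a median log2 difference of 0.45 (camera, adjusted p = 0.003; adjusted p = 0.16 with an estimated correlation). The root hair expansin EXPA18 had 1.08 ± 0.31 and EXPA15 0.48 ± 0.15 (SE), neither past the threshold by itself (limma, adjusted p = 0.18 and 0.28). In triploid TME 5 of 6 were higher with a median of 0.27 (adjusted p = 0.0153; adjusted p = 0.27 with an estimated correlation), and the slope over chromosome sets had a median of 0.21 (adjusted p = 0.00321; adjusted p = 0.15 with an estimated correlation). In triploid TFE the family did not pass: 3 of 6 were higher than in diploids (median 0.11, camera, adjusted p = 0.475). The direct test against triploid TME, with 1 of 6 higher in TFE, did not pass either (median -0.25, camera, adjusted p = 0.45). A difference between the triploid codes in this family is therefore not shown. Under quantile normalization the medians were 0.45, 0.26 and 0.21, in the same direction. EXPA7 (0.61) and EXPA18 also belong to the root marker list, whose only other measured member, PYK10, had 0.21 (adjusted p = 0.77). A larger share of root tissue in these whole seedlings was not tested. EXPA4, EXPA8 and EXPA15 also belong to the cell wall expansion list, whose 5 other members, COB, XTH16, XTH18, XTH19 and XTH33, were all lower in tetraploids, between -0.40 and -0.15, none past the threshold.

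The UGT family of glycosyltransferases, which shares UGT78D1 and UGT78D2 with the flavonoid list, lay lower in triploid TFE than in diploids, with 6 of 26 members higher and a median of -0.23 (adjusted p = 0.0148; adjusted p = 0.38 with an estimated correlation). Its members UGT72E1 and UGT74B1 had differences of -0.56 ± 0.18 and -0.41 ± 0.15 (limma, adjusted p = 0.46 and 0.49). Against the midpoint of diploid and tetraploid, triploids had a UGT median of -0.12 (adjusted p = 0.00818; adjusted p = 0.55 with an estimated correlation). The IQD family of calmodulin-binding proteins had 10 of 12 members higher in triploid TFE than in diploids, with a median of 0.39 (adjusted p = 0.0412; adjusted p = 0.35 with an estimated correlation). Quantile normalization gave -0.31 and -0.16 for UGT and 0.28 for IQD, in the same directions.

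The smallest adjusted p of tetraploid versus diploid belonged to an unnamed probe set, the 1 with a difference of -1.13 between triploid TFE and triploid TME, with signals of 161 ± 12.5 (SD, n = 3) in tetraploids, 141 ± 12.1 (n = 3) in triploid TME, 65.1 ± 11.6 (n = 3) in triploid TFE and 32.1 ± 2.77 (n = 2) in diploids (limma, adjusted p = 5.5e-05). The unnamed probe set with -2.12 between the triploids had 276 ± 53, 119 ± 46.3, 27.5 ± 10.9 and 34.6 ± 9.9 in the same groups, with log2 differences from diploids of 3.01 in tetraploids (adjusted p = 0.00067) and -0.37 in triploid TFE (adjusted p = 0.72). A probe set shared by several genes was higher than in diploids in tetraploids and triploid TME, by 1.36 and 1.14 (adjusted p = 0.0015 and 0.028), and had a difference of 1.11 in triploid TFE that missed the threshold (adjusted p = 0.068). These probe sets were chosen after their values were seen.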
